A study of Mus musculus with 2 samples.

How the data were processed

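The samples were 2 biological replicates of H3K4me1 ChIP-seq on mouse embryonic intestine at day 16.5, grouped from the antibody and replicate number in the labels. Fragments were 300 to 500 bp long per the labels. The material was pooled from several embryos of both sexes in each replicate, so the spread between the replicates is one between pools. The authors deposited 4 peak lists in narrowPeak format with coordinates on mm10: one for each replicate, one for the pooled reads of both and one of replicated peaks. Per the deposited read-me text, the peaks of replicate 1 and of the pool were called against 2 control alignment files and those of replicate 2 against 1, and technical replicates were merged before calling. The aligner, the peak caller and the rule that selected the replicated peaks are not given in the sources used here.

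The deposited lists give for each peak the authors' fold enrichment over control, a linear ratio, and the −log10 of a q value computed within its own list. They also give the summit as an offset in bases from the peak start, per the deposited format. These values were used only to describe, rank or filter peaks within a list. The deposited lists contain many weak peaks: 9.19% of replicate 1 peaks and 23.1% of replicate 2 peaks had a q above 0.05. Read depth is unknown. Depth, the control used and the threshold all set how many peaks a list holds, so differences in coverage between the replicates are not differences in the amount of the mark. The replicated list was found whole inside the pooled list, and 65.9% of its peaks overlapped peaks of both replicates by at least 50% of either peak. In it, 24.5% of peaks had no base in a replicate 2 peak and 11.1% had none in a replicate 1 peak. It is therefore not a list of peaks present in both replicate lists, and it served as an alternative, and as the list from which the peaks of highest fold enrichment and the longest stretches were named.

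Coordinates were compared with the GRCm38.p6 assembly and GENCODE M21 annotation, the build that mm10 names. No peak ran past a chromosome end, and 2 peaks of replicate 1 touched an assembly gap. Peaks lay on 20 chromosomes, the 19 autosomes and the X. All coordinates are 1-based on this build. Analyses used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.

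A peak counted as shared when at least 50% of its length was covered by peaks of the other replicate. Expected shares came from 100 random placements of the same peaks on the same chromosome outside assembly gaps, with one-sided permutation p-values. For annotation, each covered base was assigned to promoter (1 kb on each side of a protein-coding TSS), exon, intron or intergenic sequence, in that order, and compared with 100 placements by two-sided permutation. In both tests each peak was placed on its own, without matching on GC content, repeats or neighbouring peaks. A TSS was called CpG-rich when the observed over expected CpG ratio in the 1 kb around it was at least 0.6.

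For gene lists, the kb covered by peaks within 50 kb of the TSS was computed for 21701 protein-coding genes, after leaving out 54 with a shared symbol. All 516 listed genes matched the annotation. The 25 lists comprised 11 of cell types in the gut wall, 10 of other organs or of every cell, and 4 of signalling pathways. Bmp4, Bmp5, Grem1, Gli1, Gli2 and Gli3 stand in the gut mesenchyme list and in a pathway list. The list median was placed among 10000 random lists of the same size, matched on 5 classes of gene length and 5 of the number of TSSs in the window. A list stood apart when its percentile was at least 97.5 or at most 2.5 in both replicates. Motifs were counted on either strand within 250 bp of the summit of peaks over 1 kb from any protein-coding TSS. Their background was 500 bp sequences 5 kb on each side that lay outside gaps and the peaks of either replicate or the pooled list. A motif stood apart when its ratio differed from 1 by over 2 SD in both replicates, over those of the 19 autosomes that gave a ratio. Rare motifs such as NFI had a ratio on few autosomes. The 2 SD limit was not fixed before the data were examined, unlike the lists, motifs, windows and tests of the main comparisons. Some further tests were chosen after the data were seen, as said where they appear.

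Genes were named by a rule fixed before the data were examined. It took the 2 most and the least covered members of each gut list, and the most covered member of every other list. It also took the 10 genes with the highest lower value of the 2 replicates, the most and least covered Hox gene of each cluster, the 5 replicated peaks of highest fold enrichment and the 10 longest stretches. For the 10 genes, only the first of genes whose TSSs lay within 50 kb of each other was kept. Other genes named in the text were chosen after their values were seen.

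The overlap and gene list methods and the motif search were tested on simulated data, and the annotation, TSS, Hox and X chromosome methods were not. Known shares of overlap were recovered within 1.92 percentage points over 151871 simulated peaks. Of 200 random lists of 20 genes with no added coverage in replicate 1, 6% were called. Adding 2 kb to every member of such a list gave a call in 30% of 50 lists, and adding 5 kb in 100%, so differences of 2 kb or less would mostly be missed. All planted motif sites were found in random sequence, at 100% for each of 20 motifs. This checked only the search for a consensus. The ratio to the background and the 2 SD limit were not simulated. The alternatives chosen before were stricter peaks (a −log10 q of at least 5), other overlap rules, other promoter widths, windows, matching and backgrounds, the replicated list, and each replicate alone. A pair of alternatives for the gene lists was added after seeing the data: leaving out X-linked genes, and matching random lists on GC content as well. No comparison between groups was possible with 1 group.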

Results

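H3K4me1, the monomethylation of lysine 4 on histone H3, marks enhancers and the flanks of promoters. Its distribution was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the intestine of B6NCrl mouse embryos at day 16.5, a stage at which villi are forming and the tissue holds epithelium, mesenchyme, smooth muscle, enteric neurons, vessels and mesothelium. The data comprised 1 group of 2 biological replicates, each made from embryos of both sexes. Replicate 2 was pooled from 41 embryos, and the number pooled for replicate 1 was not given. With 1 group there was no comparison between conditions. The questions were how far the peaks repeated between replicates, where in the genome they lay, and which genes, gene groups and sequence motifs they surrounded. Read depth is unknown, because the files used here list peaks and not reads, so no interval for counting error is given.

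Replicate 1 had 151871 peaks covering 60.8 Mb, or 2.31% of the assembly, and replicate 2 had 115106 peaks covering 39.2 Mb, or 1.49%. The mean over the replicates was 133488 ± 25997 peaks (SD, n = 2) and 50.02 ± 15.2 Mb. Median peak length was 300 bp in replicate 1 and 263 bp in replicate 2. The authors' fold enrichment over control, which is each peak's own value, had a median of 3.13 in replicate 1 and 3.42 in replicate 2. The authors' pooled list held 142788 peaks over 66.2 Mb. Their list of replicated peaks held 98879 peaks over 55.0 Mb.

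The strongest H3K4me1 peaks were the ones that both replicates shared most often. In the top 10% of replicate 2 by fold enrichment, 88.7% of peaks had at least 50% of their length inside replicate 1 peaks, against 50.5% in the bottom 10% and a lowest share of 46.1% in the eighth of the 10 groups. The same shares for replicate 1 peaks inside replicate 2 were 71.4% and 20.6%. Over the whole lists, 34.7% of replicate 1 peaks and 59.6% of replicate 2 peaks were shared. Random placement of the peaks on their own chromosomes gave 1.61% ± 0.03 and 2.62% ± 0.05 (SD over 100 placements), so the observed shares were 21.6 and 22.8 times higher (permutation test, one-sided p = 0.0099 for each, the smallest that 100 placements can give). The bases covered in both replicates came to 24.7 Mb, 32.8% of the bases covered in either. Because fewer bases were covered in replicate 2, a peak of replicate 1 had less to overlap. At a −log10 q of at least 5, the share of replicate 1 peaks fell to 14.01% of 21686, set against 5977 peaks left in replicate 2. The share of those 5977 peaks was 63.8%, and the ratios to random placement rose to 71.3 and 91.03.

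**Figure D1:**
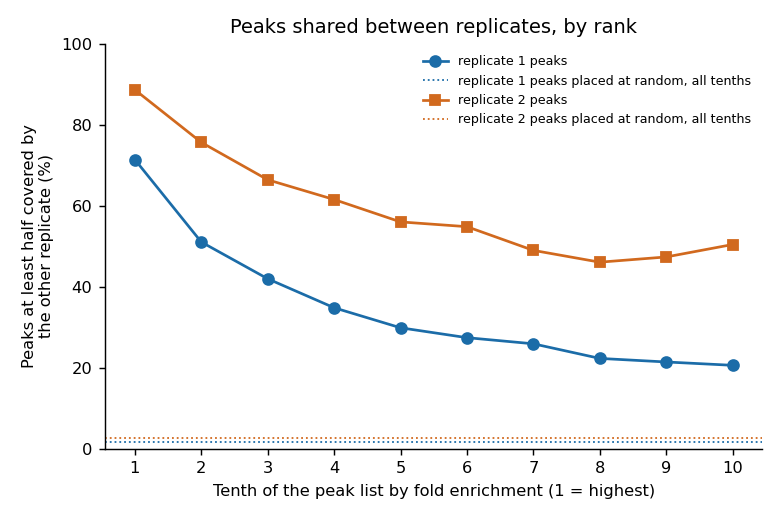
Share of peaks (%, vertical axis) with at least 50% of their length covered by the other replicate's peaks, in 10 equal groups of each replicate's list ranked by fold enrichment (horizontal axis, 1 is highest). Lines with points show replicate 1 and replicate 2, and dotted lines show the mean over whole lists placed at random; the share falls from 71.4% to 20.6% in replicate 1, and in replicate 2 from 88.7% to 46.1% in group 8 before 50.5% in group 10.

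H3K4me1 peaks lay mostly in introns. Compared with random placement they were enriched at promoters and depleted between genes. Introns of protein-coding genes held 53.6% ± 0.6 of covered bases (SD, n = 2), 1.46 ± 0.01 times the share of randomly placed peaks. Promoters, taken as 1 kb on each side of a transcription start site (TSS), held 14.4% ± 0.2, or 5.33 ± 0.03 times the random share. Exons held 5.47% ± 0.07, a ratio of 1.64 ± 0.02. Intergenic sequence held 26.5% ± 0.8, a ratio of 0.464 ± 0.013. Every class differed from random placement in each replicate (permutation test, two-sided p = 0.0198, the smallest that 100 placements can give). The placements kept neither the clustering of peaks nor their GC content, so this p-value concerns uniform placement alone. The median distance from a summit to the nearest protein-coding TSS was 13.2 kb in replicate 1 and 11.7 kb in replicate 2, and 55.2% and 53.0% of summits lay over 10 kb from any such TSS.

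Around CpG-rich promoters the mark formed a pair of flanks with a dip at the start site. Peaks covered 5.47% ± 2.48 of the 10075 CpG-rich TSSs at the start site itself (SD, n = 2). Coverage rose to 32.6% ± 8.3 downstream, at 1200 bp in replicate 1 and 1100 bp in replicate 2. Upstream it reached 19.6% ± 5.9, at 600 bp in both replicates. At 10 kb, averaged over both sides, it was 4.48% ± 1.25. The 11680 CpG-poor TSSs had a flatter profile: 9.27% ± 3.19 were covered at the start site, 10.05% ± 2.33 at 300 bp upstream and 9.79% ± 3.06 at 200 bp downstream. The dip at CpG-rich TSSs was present in each replicate, from 38.5% to 7.23% in replicate 1 and from 26.7% to 3.72% in replicate 2.

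**Figure D2:**
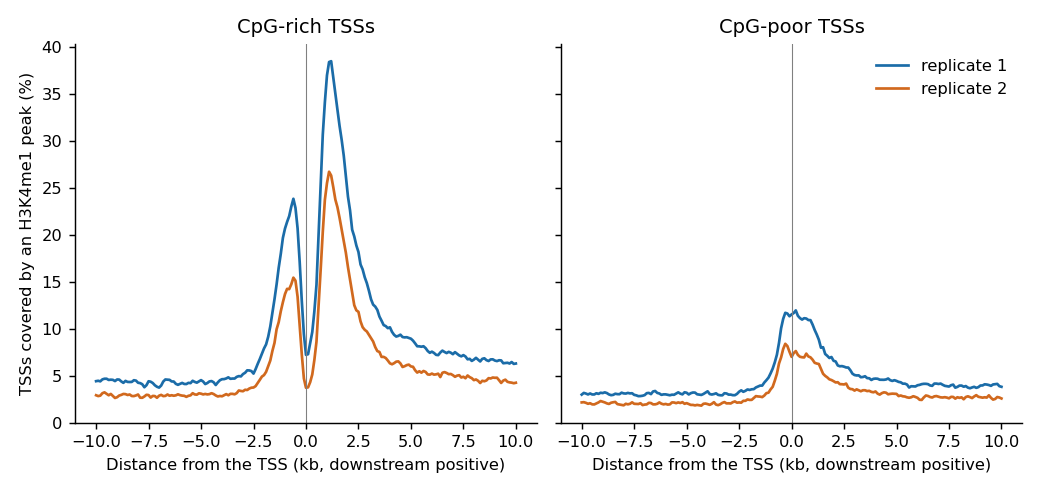
Share of protein-coding TSSs covered by an H3K4me1 peak (%, vertical axis) at distances up to 10 kb from the TSS (kb, horizontal axis, downstream positive), for CpG-rich TSSs (left) and CpG-poor TSSs (right). Lines show the 2 replicates. At CpG-rich TSSs the downstream maximum is 38.5% in replicate 1 and 26.7% in replicate 2, with a dip at the TSS between the flanks.

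Gut epithelium transcription factor genes and epithelial progenitor genes had more H3K4me1 around them than matched random genes. Coverage was measured as the kb of peaks within 50 kb of the TSS, a window of 100 kb, for which the median of 21701 protein-coding genes was 2.38 ± 0.89 kb (SD, n = 2). Gut epithelium transcription factors had a median of 5.57 ± 2.31 kb over 24 genes, against 1.85 kb for random lists matched on gene length and TSS density, and 21 of the 24 exceeded the genome median. Tcf7l2, a transcription factor of the Wnt pathway (chromosome 19, 55741820 to 55933654), had 18.8 ± 5.7 kb. Cdx1, an intestinal homeobox gene (chromosome 18, 61018862 to 61036199), had 17.2 ± 5.0 kb. The least covered was Hnf4g, a nuclear receptor gene of the enterocyte, with 0.465 ± 0.334 kb. Epithelial progenitor genes and Wnt targets stood higher still, at 7.61 ± 2.42 kb over 18 genes against 1.62 kb. Ephb2, which encodes a receptor that positions cells along the crypt (chromosome 4, 136647539 to 136835988), had 19.8 ± 5.4 kb. Lgr4, an R-spondin receptor gene, had 14.8 ± 5.0 kb, while Myc had 1.49 ± 0.20 kb. Both lists lay at or above the 99.9th percentile of 10000 random lists in each replicate. With random lists also matched on GC content, a setting chosen after seeing the data, the progenitor list stayed at the 99.9th percentile or above in each replicate. The transcription factor list then fell to 99.6 in replicate 1 and 97.4 in replicate 2, just under the upper limit, which was the top 2.5% of random lists in both replicates.

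The lists of differentiated epithelial genes did not pass that limit in both replicates with 50 kb on each side of the TSS. Enterocyte genes had a median of 4.80 ± 0.65 kb over 28 genes, at the percentiles 96.4 and 99.7. The enterocyte list passed in the window of 20 kb on each side, at 99.2 and 99.7, and without X-linked genes, a setting chosen after seeing the data, at 99.1 and 99.4. Lgals4, which encodes a galectin of the brush border (chromosome 7, 28833854 to 28841708), had 18.5 ± 3.2 kb, and Cldn7, a tight junction gene, had 13.7 ± 4.9 kb. Sis, which encodes the disaccharidase sucrase-isomaltase, had 0.091 ± 0.129 kb. Goblet and enteroendocrine genes had 2.97 ± 0.98 kb over 24 genes, at the percentiles 95.1 and 95.6. With GC-matched random lists this list fell to 65.7 and 69.9, and the enterocyte list was at 94.0 and 99.6. Gip and Chga, expressed in enteroendocrine cells, had 12.0 ± 3.9 kb and 7.36 ± 1.27 kb, whereas Muc2, the main secreted mucin gene of goblet cells, had 0.258 ± 0.365 kb.

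Among the other cell types of the gut wall, the smooth muscle list alone stood above its random lists. Its 22 genes had a median of 5.77 ± 1.90 kb against 2.51 kb, at the percentiles 99.7 and 99.6. Csrp1, a muscle LIM protein gene (chromosome 1, 135720061 to 135752232), had 15.1 ± 2.8 kb and Des, the desmin gene, had 13.9 ± 2.8 kb, while Mylk had 0.501 ± 0.091 kb. This call ended with GC-matched random lists, at the percentiles 93.5 and 89.5. Gut mesenchyme genes, 29 in all, had 2.59 ± 1.68 kb, at the percentiles 96.9 and 72.5. Pdgfrb had 17.3 ± 4.5 kb, in a window that it shares with Cdx1, and the mesenchymal forkhead gene Foxf1 had 10.2 ± 3.0 kb. Bmp5 had 0.423 ± 0.598 kb. The enteric nervous system list had 2.13 ± 1.35 kb over 24 genes, at the percentiles 60.4 and 26.1. With GC-matched random lists it stood at 16.6 and 1.75. Its members ranged from Tlx2, a homeobox gene of enteric neurons, with 13.1 ± 0.7 kb, and Prph with 10.8 ± 2.6 kb, to the X-linked myelin gene Plp1 with none.

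Endothelial genes had 3.33 ± 1.00 kb over 22 genes, at the percentiles 91.2 and 94.1. Eng, the endoglin gene, had 21.3 ± 3.2 kb and Egfl7 had 10.6 ± 5.7 kb, against 0.171 ± 0.241 kb for Emcn. The Egfl7 window overlaps that of Notch1. Mesothelial genes had 3.76 ± 0.66 kb over 15 genes, at 82.2 and 93.4. The keratin genes Krt8 and Krt18, which lie next to each other on chromosome 15 and are also used by gut epithelium, had 17.4 ± 2.9 kb and 16.6 ± 4.1 kb, and Gpm6a had none. Immune genes had 2.41 ± 0.67 kb over 26 genes, at 31.1 and 44.3, led by Cd4 with 12.5 ± 2.1 kb and Fcer1g with 11.4 ± 1.2 kb. Ptprc, the pan-leukocyte gene for CD45, had none. With GC-matched random lists the immune list was at 1.91 and 5.9, endothelium at 48.05 and 57.04, and mesothelium at 49.29 and 74.6. Erythroid genes were the least covered list, with 1.24 ± 0.49 kb over 14 genes against 2.60 kb, at 8.10 and 9.39. This low value rested on 2 X-linked members, Gata1 and Alas2. Without X-linked genes the erythroid median was 2.64 ± 0.93 kb, equal to that of its random lists, at the percentiles 48.95 and 51.3. Nfe2 had 15.6 ± 5.9 kb and Slc4a1 had 9.90 ± 2.30 kb, while Rhag had none. With GC-matched random lists the erythroid list fell to the percentile 2.07 in each replicate, within the bottom 2.5%, with its X-linked members still included.

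Of the 10 lists for organs outside the gut or for genes used in every cell, the pancreas list passed the limit in both replicates. Its 18 genes had 4.91 ± 2.57 kb against 1.55 kb, at the percentiles 99.95 and 98.71, with Ctrb1, the chymotrypsinogen gene, at 21.7 ± 3.1 kb. The pancreas list was mixed, with 3 members in the top 5% of all genes and 3 with no peak in either replicate. Its call was lost with GC-matched lists, at 97.3 and 76.5, with unmatched lists, at 98.4 and 89.3, and in a window of 20 kb on each side, at 88.6 and 86.1. Housekeeping genes had 5.82 ± 1.52 kb, at 97.4 and 98.1, with Eef2 at 17.1 ± 3.3 kb, and passed the limit in both replicates with GC-matched lists, with unmatched lists and in the other 2 windows tried. The forebrain list had 2.70 ± 1.11 kb, at 96.2 and 94.0, led by Bcl11b with 13.5 ± 3.3 kb. It passed with a window of 20 kb on each side of the TSS or with the gene body plus 20 kb. The forebrain list was far from the limit with unmatched lists, at 64.5 and 56.6, and with GC-matched lists, at 76.7 and 68.1.

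Skeletal muscle genes had 3.63 ± 0.80 kb, at the percentiles 88.2 and 95.4. Their leading member Tnnt3 had 28.0 ± 6.5 kb in a window that also holds Mrpl23, one of the 10 most covered genes. Photoreceptor and lens genes had 4.32 ± 1.85 kb, at 95.7 and 88.6, led by Gnat1 with 25.1 ± 4.8 kb. Stomach and lung genes had 3.12 ± 0.73 kb, at 71.9 and 83.0, with Ager at 14.4 ± 3.7 kb. Heart genes had 2.57 ± 0.85 kb, at 72.6 and 76.0, with Myl7 at 11.6 ± 0.8 kb. Sperm genes had 3.74 ± 1.67 kb, at 78.9 and 64.2, with Prm1 at 8.03 ± 2.09 kb. Liver genes had 1.73 ± 0.80 kb, at 39.4 and 31.9, with Apoh at 10.9 ± 2.6 kb. Epidermis genes had 1.34 ± 0.44 kb, at 13.4 and 17.5, with Grhl3 at 13.8 ± 2.7 kb. Several of these lists moved to the low end with GC-matched random lists. Skeletal muscle was then at 2.36 and 8.2, heart at 1.85 and 2.7, and stomach and lung at 4.6 and 12.9. Epidermis was at 1.77 and 2.98 and sperm at 25.3 and 9.6. Liver stood at 49.5 and 41.5, and photoreceptor and lens at 77.1 and 48.8. None of them passed the lower limit in both replicates.

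All 4 signalling pathway lists stood above their random lists in both replicates. Notch pathway genes had the highest median of the 25 lists, 8.20 ± 2.10 kb over 20 genes against 2.20 kb, and 19 of the 20 exceeded the genome median. Notch1, which encodes a Notch receptor (chromosome 2, 26457903 to 26516663), had 25.6 ± 5.6 kb. BMP pathway genes had 5.07 ± 1.55 kb over 20 genes against 1.60 kb, led by the inhibitory SMAD gene Smad7 (chromosome 18, 75367529 to 75395935) with 31.1 ± 3.8 kb. Hedgehog pathway genes had 5.4045 ± 1.65 kb over 17 genes against 2.04 kb, with the receptor gene Ptch1 at 13.6 ± 5.4 kb. Hippo pathway genes had 4.73 ± 1.73 kb over 21 genes against 2.11 kb, with the transcription factor gene Tead1 (chromosome 7, 112679318 to 112906807) at 22.0 ± 4.8 kb. The lowest percentile of any of these lists in either replicate was 99.1. With GC-matched random lists, BMP at 99.5 in each replicate and Hippo at 99.2 and 98.7 still passed, whereas Notch at 94.96 and 94.83 and Hedgehog at 89.0 and 88.8 did not. The Hippo call was also lost in the window of 20 kb on each side, at a mean percentile of 90.3, and with unmatched random lists, at 95.8, as was the Hedgehog call with unmatched lists, at 97.3.

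In total, 8 of the 25 lists passed the upper limit in both replicates and 0 passed the lower one, where chance gives 0.625 lists at each end in a single replicate. These percentiles describe the 2 libraries and carry no p-value, since genes are not replicates. Only 3 lists, the epithelial progenitor, Notch and BMP lists, stayed above when peaks with a −log10 q of at least 5 were used. That cut left most list medians in replicate 2 at 0, so the lost calls say little about single lists.

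**Figure D3:**
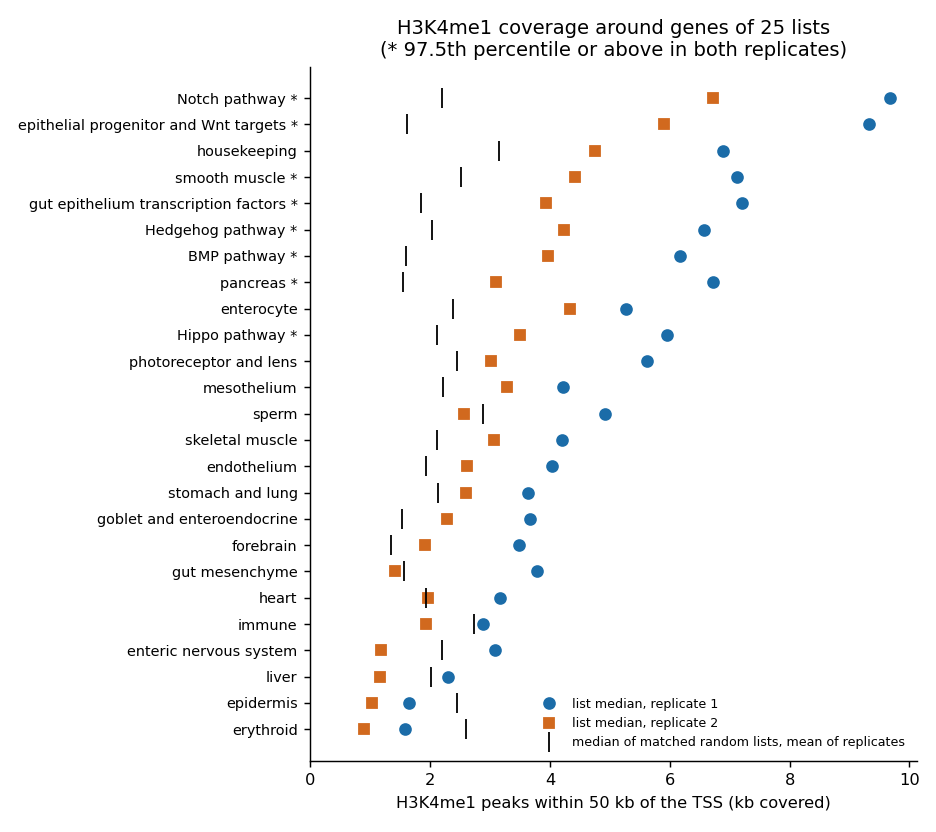
Median kb covered by H3K4me1 peaks within 50 kb of the TSS (horizontal axis) for the 25 gene lists (vertical axis). Circles show replicate 1, squares replicate 2, and black ticks the median of matched random lists averaged over replicates; an asterisk marks the 8 lists in the top 2.5% of random lists in both replicates, from Notch with 8.20 kb to Hippo with 4.73 kb on average.

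Rara, Rxra and Ski led the ranking of all genes by the H3K4me1 around them. Of genes whose TSSs lay within 50 kb of each other, only the first was kept. Rara, which encodes a retinoic acid receptor (chromosome 11, 98927818 to 98974942), had 40.5 ± 4.0 kb of its 100 kb window covered. Rxra, the gene of its dimer partner (chromosome 2, 27676440 to 27762957), had 37.9 ± 2.7 kb. The TGF-beta repressor gene Ski on chromosome 4 had 40.2 ± 7.1 kb and the effector gene Smad3 on chromosome 9 had 36.6 ± 6.8 kb. The others were Mrpl23 with 37.2 ± 5.6 kb, Myh9, a non-muscle myosin gene, with 37.1 ± 6.0 kb, Zmiz1 with 36.9 ± 4.0 kb, Gm48551 with 36.9 ± 4.8 kb, Ahdc1 with 35.8 ± 3.9 kb and Cbarp with 35.1 ± 5.2 kb. Gm48551 and Cbarp lie among other genes on chromosome 10 and share their windows with 8 and 7 further TSSs. The windows of Mrpl23, Rara, Ski and Ahdc1 also hold the TSSs of Tnnt3, Cdc6, Faap20 and Fgr, in that order.

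Among the peaks with the highest fold enrichment in the replicated list, 4 of 5 had their summit in an intron. A pair lay in Ncor2, a nuclear receptor corepressor gene on chromosome 5, at 125156536 to 125160501 with 9.75-fold enrichment and at 125150498 to 125153645 with 8.59-fold. An intron of Rara held a peak of 7921 bp with 9.60-fold enrichment (chromosome 11, 98938214 to 98946134). An intron of Ccdc85c held one with 9.45-fold enrichment (chromosome 12, 108243929 to 108245965). The remaining one was intergenic, 9126 bp from the TSS of Mrpl23 (chromosome 7, 142541812 to 142543639), with 9.05-fold enrichment. Each of the 5 was at least 80.1% covered by peaks in both replicates.

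Joining replicated peaks within 1 kb of each other gave 61137 stretches with a median of 0.613 kb, of which 192 reached 10 kb. The longest, 30.1 kb, overlapped Zfpm1, which encodes a cofactor of GATA factors (chromosome 8, 122301620 to 122331716). The next, 28.7 kb, overlapped Samd4b and Pak4 (chromosome 7, 28568487 to 28597222). Stretches of 26.7 kb in Ccdc85c, 26.0 kb in Myh9, 24.7 kb in Dab2ip, 24.2 kb in Actn4 and 23.7 kb in Ahdc1 followed. The last of the 10 longest were 23.2 kb over Fgfr2 and Ctbp2, 22.8 kb in Ror2 and 22.5 kb in Sept9. Ccdc85c, Myh9 and Ahdc1 thus came up in this ranking and in one of the others.

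The Hox genes, which pattern the body axis and the gut along its length, were covered unevenly. The HoxA cluster on chromosome 6 had 19.7% ± 5.6 of its bases in peaks (SD, n = 2), HoxB on chromosome 11 had 13.2% ± 5.0, HoxD on chromosome 2 had 8.82% ± 3.0 and HoxC on chromosome 15 had 6.49% ± 3.99. The replicate values were 23.7% and 15.8% for HoxA, 16.7% and 9.65% for HoxB, 9.31% and 3.67% for HoxC and 10.9% and 6.70% for HoxD. The order HoxA, HoxB, HoxD, HoxC was the same in each replicate. Each share was taken over the span from the first to the last gene of the cluster. The HoxB span includes the stretch between the end of Hoxb13 (96197447) and the start of Hoxb9 (96271457). That stretch holds no other Hox gene and lowers or raises the HoxB share with its own coverage, so the place of HoxB in this order depends on the span chosen. Within clusters, with 1 kb added on each side of a gene, Hoxa3 was the most covered of HoxA at 31.2% ± 7.6 and Hoxb3 of HoxB at 38.2% ± 9.996. Hoxc6 led HoxC at 19.8% ± 8.3 and Hoxd1 led HoxD at 26.5% ± 11.8. Hoxa11 and Hoxd12 had no peak in either replicate, and Hoxc12 at 1.18% ± 1.67 and Hoxb7 at 5.60% ± 7.91 were the least covered of their clusters. Among the most posterior genes, chosen after their values were seen, coverage was 24.98% ± 8.85 for Hoxa13, 12.1% ± 8.5 for Hoxd13, 6.92% ± 4.96 for Hoxb13 and 2.38% ± 3.36 for Hoxc13, which had no peak in replicate 2. The annotated spans of Hoxa3, Hoxc5, Hoxd3 and Hoxd4 overlap neighbouring Hox genes, so their values are not separate.

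**Figure D4:**
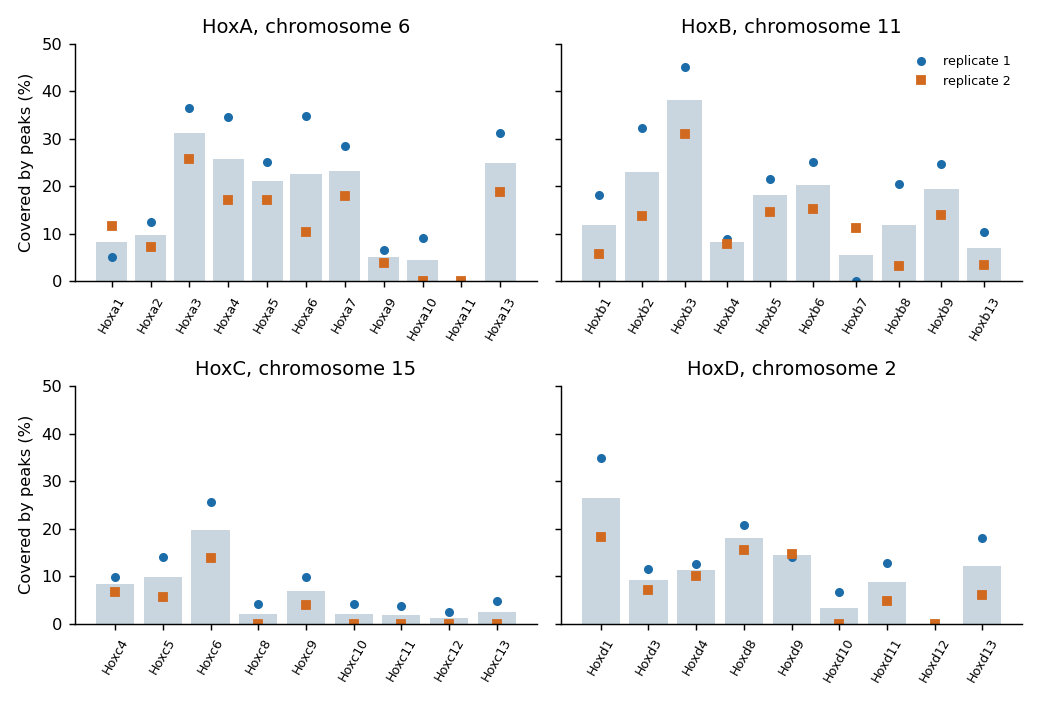
Share of each Hox gene's body plus 1 kb on each side that was covered by H3K4me1 peaks (%, vertical axis), for the 4 clusters with genes in order of their number (horizontal axis). Bars show the mean of the 2 replicates, circles replicate 1 and squares replicate 2; Hoxb3 reaches 38.2% on average and Hoxa11 and Hoxd12 are at 0.

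Distal H3K4me1 summits were richer in KLF, bHLH E-box and TEAD motifs than sequence 5 kb away. In the 20000 distal peaks of highest fold enrichment per replicate, KLF matches (CCMCRCCC) were 1.80 ± 0.11 times as dense as in the flanks (SD, n = 2), E-box matches (CAGCTG) 1.70 ± 0.02 times and TEAD matches (RCATTCCW) 1.48 ± 0.003 times. Each of these ratios exceeded 1 on 19 of 19 autosomes in both replicates and by over 2 SD over the autosomes. CDX (TTTATKR) and HOX homeobox (TAATTA) matches were sparser than in the flanks, at 0.741 ± 0.004 and 0.713 ± 0.024 times, on 19 of 19 autosomes in both replicates. The peaks had a GC content of 49.95% and 49.6% against 45.9% and 45.8% in the flanks. Against random genomic sequence matched on GC content, CDX and HOX changed direction, to 1.14 ± 0.01 and 1.19 ± 0.01, and neither then passed the 2 SD limit. KLF at 1.39 ± 0.02 and E-box at 1.30 ± 0.01 still passed, with smaller ratios than against the flanks. TEAD at 1.53 ± 0.001 did not pass, although its ratio had not fallen. Its SD over the autosomes in replicate 2 rose from 0.171 to 0.294.

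FOX matches had a ratio of 1.38 ± 0.02, above 1 on 18 and 19 of 19 autosomes in the replicates, AP-1 1.25 ± 0.01 on 17 autosomes in each, and HNF4 1.86 ± 0.16 on 17 and 18. None of these passed the 2 SD limit in both replicates. Against the GC-matched background FOX was at 1.66 ± 0.05, HNF4 at 2.03 ± 0.07 and AP-1 at 1.34 ± 0.03. There the FOX and HNF4 ratios were above those of KLF and E-box, but their SD over the autosomes was wider. None of the 3 passed the limit there. With all distal peaks in place of the top 20000, FOX at 1.34 and AP-1 at 1.23 passed it, on 19 of 19 autosomes in each replicate. NFI matches had the highest ratio, 6.90 ± 0.51, from only 49 and 33 matches in the peaks. CTCF matches had 2.32 ± 0.01, from 162 and 144. Ratios were 1.64 ± 0.17 for HNF1, 1.44 ± 0.01 for GLI, 1.18 ± 0.02 for ETS, 1.12 ± 0.09 for the SRF CArG box, 1.05 ± 0.003 for GATA, 1.05 ± 0.05 for the TP53 family, 0.983 ± 0.010 for RUNX, 0.906 ± 0.065 for SOX and 0.440 ± 0.165 for PHOX2, none past the limit. PHOX2 had only 15 and 27 matches in the peaks. Against the GC-matched background PHOX2 was at 1.02 ± 0.68 and RUNX at 1.24 ± 0.07, neither past the limit. The REST consensus had no match in the top 20000 peaks or their flanks. With all distal peaks it had 2 matches in replicate 1 peaks and 1 in replicate 2 peaks.

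The X chromosome was almost bare of H3K4me1 peaks. Peaks covered 0.124% of the X in replicate 1 and 0.0596% in replicate 2, against autosomal medians of 2.62% and 1.69%, a ratio of 0.0414 ± 0.0087 (SD, n = 2). Against autosomal windows matched on GC content and TSS number, a test chosen after the result was seen, the mean ratio was 0.141. The lowest autosome, chromosome 3, had 1.63% and 1.00%, and the highest, chromosome 11, had 4.20% and 2.85%, so the X lay outside the autosomal range in both replicates. The X carried 742 peaks in replicate 1 and 407 in replicate 2. Of its 948 protein-coding genes, 57.2% had no peak within 50 kb in either replicate, against 15.3% of autosomal genes. Of the 742 X peaks in replicate 1, 91 were shared with replicate 2, or 12.3%. Bcor, which encodes a corepressor of BCL6, was the nearest gene to 23 of these 91 and was singled out after its values were seen. X-linked members of the gene lists, such as Plp1, carry this low coverage into their lists.

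**Figure D5:**
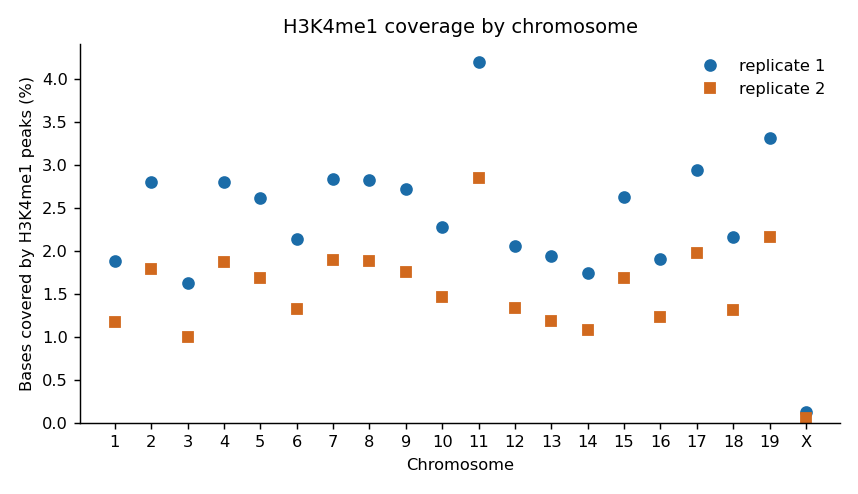
Share of bases covered by H3K4me1 peaks (%, vertical axis) on each of the 19 autosomes and the X (horizontal axis). Circles show replicate 1 and squares replicate 2; the X has 0.124% and 0.0596%, below every autosome, whose lowest values are 1.63% and 1.00% on chromosome 3.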

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

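In the comparisons above, the pooled list served only to keep motif backgrounds free of peaks, and through the replicated list that lies inside it. The pooled list held peaks that neither replicate list contains. Of its 142788 peaks, 13039, or 9.13%, had no base in a peak of either replicate and were set apart for that reason. Peaks called on the pooled reads need not be in either replicate list, so their presence alone shows nothing further. They were weak and short, with a median fold enrichment of 2.58 against 3.10 for the other pooled peaks and a median length of 222 bp against 356 bp. The authors' replicated list includes 2590 of them.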

How the results depend on the processing

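Random lists matched on GC content and the omission of X-linked genes were tests chosen after the result was seen. Of 115 alternative values for the main results, 88 held: values with a test kept their direction and their side of its threshold, whatever their size, and the others stayed within the replicate spread, the interval or, for counts, a factor of 1.5. With n = 2 a single replicate always lies within the replicate spread. Values of 1 replicate alone that were judged by that spread therefore held by construction and show nothing about robustness. Sizes of tested values still changed, to 14.01% of replicate 1 peaks shared at a −log10 q of at least 5, 34.5% of replicate 2 peaks with a reciprocal overlap, and a promoter ratio of 3.35 with all annotated genes. The shares of peaks shared between replicates kept a permutation p of 0.0099 under all 4 overlap alternatives, and the 4 annotation classes kept their direction and permutation p under every alternative run. A −log10 q of at least 5 gave a mean of 13831.5 peaks and 10.6 Mb per replicate, a ratio of the X to the autosomal median of 0.00562, and TSS coverage of 1.04% at and 9.92% downstream of CpG-rich TSSs and 1.85% at and 2.13% downstream of CpG-poor TSSs. The same limit gave 2.71% for HoxA, 2.37% for HoxB, 0.805% for HoxC and 2.13% for HoxD, and 3 lists above, 1 motif above and 1 motif below. The calls of KLF at 1.82, TEAD at 1.49 and CDX at 0.714 were lost there with ratios about as far from 1, as the SD over autosomes in replicate 2 was wider. In replicate 2 it left most list medians at 0, so it says little about single lists there. In the replicated list the X ratio was 0.0306. Ranked by −log10 q, the shared peaks were 73.5% of the top 10% and 18.1% of the bottom 10% in replicate 1 and 90.0% and 43.2% in replicate 2. With an overlap of 1 bp the same shares were 87.9%, 32.8%, 93.8% and 62.7%. Using all distal peaks gave 5 motifs above, adding FOX at 1.34 and AP-1 at 1.23, and a GC-matched background gave 0 motifs below, with the CDX ratio reversed to 1.14 and the HOX homeobox ratio to 1.19. Random lists also matched on GC content gave 4 lists above and 1 below. Of the 8 lists above in the main setting, 3 kept their call there, and the housekeeping list joined them. Leaving out X-linked genes kept all 8, added the enterocyte list, and moved the erythroid list from a mean percentile of 8.74 to 50.1. Without replicate 1 the enterocyte list at 99.66 and the housekeeping list at 98.13 passed their limits, and without replicate 2 the FOX motif at 1.396 did. The NFI motif at 7.26 passed without replicate 1, over the 5 autosomes that gave a ratio. Fewer peaks lower the numbers, Mb and coverage by construction; for the X ratio and the other changes the cause was not tested. Read depth is unknown, and weak peaks may be missing from either list for that reason alone.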

Other observations

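The tests of the X chromosome and of the 8 lists below were chosen after the result was seen, as were the gene families and GC groups described here and the split by list of the test with equal peak numbers. Of all protein-coding genes, 17.1% had no H3K4me1 peak within 50 kb of the TSS in either replicate, and this share differed widely between gene families. Among families grouped by the start of their symbol, with at least 20 members each, the 1133 olfactory receptor genes (Olfr) had a median of 0 kb within 50 kb of the TSS, and 83.5% had no peak in either replicate. The share without a peak was 93.6% of 329 vomeronasal receptor genes (Vmn), 96.2% of 26 prolactin family genes (Prl) and 95.5% of 22 major urinary protein genes (Mup). The alpha-defensin genes (Defa), which Paneth cells of the postnatal crypt express, had no peak for 95.5% of 22 members. Families of genes used mainly outside the gut varied: 80.95% of 21 late cornified envelope genes (Lce), 82.4% of 34 secretoglobin genes (Scgb), 61.5% of 26 Serpinb genes and 59.6% of 57 keratin-associated genes (Krtap) lacked a peak, against 13.8% of 29 Spata genes, named for spermatogenesis. None of the 53 keratin genes (Krt), some of which gut epithelium uses, lacked one, and their median of 1.59 ± 0.54 kb was below that of all genes, 2.38 kb. The families were not matched on GC content, and none was tested against random genes. At the other end, Abhd genes, which encode hydrolase fold proteins, had 8.52 ± 2.14 kb over 20 genes (SD, n = 2), and Arhgef genes, which encode Rho exchange factors, had 6.02 ± 1.34 kb over 24. Ribosomal protein genes of the large subunit (Rpl) had 5.10 ± 1.13 kb over 54 genes. Solute carriers (Slc), 371 genes, had 3.07 ± 1.04 kb, and cytochromes P450 (Cyp), 100 genes, had 0.158 ± 0.223 kb. Many members of the families with no coverage lie in tandem clusters and share windows, so they are not independent. How well reads can be placed among similar copies in such clusters was not measured. A missing peak there need not mean that the mark is absent.

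H3K4me1 coverage followed the GC content of the surrounding 100 kb. In the 20% of genes with the lowest GC content, 38.9% on average, the median gene had 0 kb covered, and in the highest 20%, at 50.4%, it had 9.16 ± 2.30 kb. GC content was a candidate explanation for the 8 lists that stood above their random lists. For the epithelial progenitor, BMP and Hippo lists, matching random lists on 5 classes of GC content did not end the call. No percentile in either replicate fell under 98.67. Differences in GC content within a class were not matched, so this cannot exclude GC content altogether. For the gut transcription factor, smooth muscle, pancreas, Hedgehog and Notch lists the percentile averaged over replicates fell to between 86.92 and 98.5, so part of their excess may come from GC content. Their own medians did not change, and the calls ended because the random medians rose: from 1.85 to 3.22 kb for the gut transcription factors, 2.51 to 4.30 kb for smooth muscle, 1.55 to 3.34 kb for pancreas, 2.04 to 3.90 kb for Hedgehog and 2.20 to 5.64 kb for Notch. How much is GC bias of the assay and how much is regulatory sequence being rich in GC cannot be told apart, because no control signal by GC content was analysed here. No biological explanation was tested.

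The scarcity of peaks on the X was weighed against 3 explanations. Its GC content and gene density do not account for all of it, because the X was still covered only 0.141 times as much as autosomal windows of 100 kb matched on both. They may account for part of it. The matched windows were covered at 0.874% and 0.489% in the replicates, below the autosomal medians of 2.62% and 1.69%. Repeats and assembly gaps do not account for it, with a ratio of 0.0540 in bases outside them. A candidate explanation is weaker signal per site from the dosage of the X in a pool of both sexes, acting through the peak threshold. Scaling autosomal fold enrichment by 0.598, the mean of 0.5997 and 0.5959 in the replicates, gave the peak density of the X above its median fold. With autosomal windows matched on GC content and TSS number the factors were 0.722 and 0.706. These factors lie within a range of 0.5 to 0.75 that was set after the result was seen. They restate the low peak density as a scaling of fold enrichment over control, and the X dosage of the control would enter the same ratio. The factors therefore cannot decide whether dosage is the cause. The share of male embryos and the control signal on the X were not used here, and an absence of the mark from an inactive X stays open and untested.

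Some gene lists had relatively more coverage in replicate 1 than random lists did. Replicate 1 had more coverage for most genes, with a median log2 ratio to replicate 2 of 0.44 (0.5 kb added to each value). The ratio was higher for the enteric nervous system at 0.77, liver at 0.76, endothelium at 0.75 and gut mesenchyme at 0.74, each in the top 2.5% of random lists, where chance gives 0.625 of 25 lists. Matching on GC content did not end these calls, since the lowest of the 4 percentiles was 99.59 with GC-matched lists. With the same number of peaks from each replicate, the enteric nervous system and gut mesenchyme stayed at 99.82 or above. A larger number of peaks alone therefore does not account for these calls. Equal numbers did not equalise coverage. The random lists of the enteric nervous system and gut mesenchyme still had median log2 ratios of 0.18 and 0.19. Read depth and the different number of control files were not equalised, and their part was not tested. For endothelium at 96.93 and liver at 93.52 the part of peak number cannot be told apart, since the calls ended while part of the difference stayed. With equal peak numbers the median log2 ratio of endothelium was 0.43 against 0.21 in random lists, after 0.75 against 0.45, and that of liver was 0.38 against 0.18, after 0.76 against 0.43. A different share of these cell types in the 2 dissections may also underlie it, and was not tested.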
